A study of Homo sapiens with 14 samples.

How the data were processed

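Gene expression was measured in peripheral blood mononuclear cells on 14 arrays with 54675 probe sets each. Per the labels, total RNA was extracted with an RNeasy kit and amplified and labelled with biotin by the Nugen Ovation WTA protocol. The deposited values were log2 signals per probe set, normalized by the authors. The normalization method is not given in the sources used here. The values had near-equal quantiles within each set of arrays. Medians per array were 6.39 to 6.46 in set 1 and 7.00 to 7.03 in set 2, so the sets had been scaled separately. Differences were therefore taken within a set unless a rescaling is named. The series title names a genotype, but the sample labels give none, and no donor was assigned one. The number of arrays limits the precision, and every group held 2 arrays. For 2 arrays against 2, the smallest p that an exact two-sided permutation test can give is 0.33, so all p-values rest on the pooled spread of the model.

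Probe sets were named from the platform's annotation. Of the 54675, 41097 carried 1 gene symbol, 1801 carried several and 11777 carried none. A current gene record was matched for 41043 of the probe sets with 1 symbol, and symbols were updated through it. Probe sets with several symbols or none were left out, as were 59 probe sets of sex-linked genes. A probe set was kept if it exceeded the 40th percentile of all values of the fit on at least 2 arrays. Each gene was represented by its probe set with the highest mean. Among named genes with several probe sets, at least 1 other probe set had the opposite sign for 5 of 54 genes at 2 weeks, 6 of 57 at 4, 4 of 59 at 12 and 7 of 57 at 24 weeks in set 1. The numbers were 5 of 58 for the mean of these times, 14 of 52 for 24 against 2 weeks, 3 of 51 in set 2, 8 of 55 between sets and 3 of 52 for the controls. This left 14015 genes in set 1, 13071 in set 2 and 14485 in the fit over all 14 arrays. Signals at the low end of an array mix expression with background, and the filter removed the lowest probe sets only.

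Linear models were fitted with limma 3.58.1 in R 4.3.3, with version 1.17.8 of the data.table package for reading tables, on a model with 1 mean per group. Variances were moderated with eBayes, tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Each error given with ± is the standard error of the log2 difference from this model. In set 1, the 2, 4, 12 and 24 week groups were each compared with the non-pregnant controls, as was the mean of the 4 times, and 24 weeks was compared with 2 weeks. In set 2, 2 weeks was compared with its controls. Over all 14 arrays, the 2-week effect of set 2 was compared with that of set 1, and the set 2 controls with the set 1 controls. Comparisons of single times with controls in set 1 share the same 2 control arrays. Repeated arrays of a person were treated as separate arrays, and a fit with the person as a replicate block (duplicateCorrelation, consensus correlation 0.396 in set 1 and 0.321 over all arrays) was an alternative. The labels identify the arrays of 1 donor, and the deviations of a donor's times from the group means correlated at 0.54 to 0.79 across genes over 6 pairs of times. The models were tested on simulated data of the same size with 200 changed genes in 20 draws. All arrays were simulated as independent, without the correlation between arrays of a person. The shares recovered therefore do not allow for repeated arrays of a donor. At a 4-fold change, 82.4% of these genes were recovered at 2 weeks in set 1, 91.1% for the mean of the 4 times, 86.4% in set 2 and 73.5% for the difference between sets. At a 2-fold change, the shares were 27.8%, 53.4%, 24.4% and 13.0%.

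The tests, the genes to be named, the gene lists and most alternatives were fixed before the data were examined. Genes were named by this rule: the 8 largest rises and 8 largest falls past the threshold without overlap between the groups' arrays, with free places filled by genes at an unadjusted p under 0.01 that are named as not passing. To these were added the 3 members of a described list with the smallest p (4 for the type I interferon list), and genes fixed in advance, among them IFI44L, IFIT1, ISG15, MX1, OAS1, RSAD2, IFI27, USP18, IRF7, CXCL10, CCR7, FKBP5, HBB and PPBP. USP18 and CXCL10 did not pass the filter in set 2.

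The lists held 533 symbols in 28 lists, of which 12 symbols were renamed to those of the platform. The pathway lists covered type I interferon-stimulated genes, interferon-gamma-induced genes, MHC class I and MHC class II antigen presentation, interferon receptors and nucleic acid sensing, inflammatory cytokines and NF-kB targets, immediate early and heat shock genes, glucocorticoid-responsive genes, T cell inhibitory receptors and effector regulators, cell cycle, ribosomal proteins, mitochondrial respiratory chain, and complement and phagocytic receptors. The marker lists covered T cells, naive T cells, regulatory T cells, cytotoxic lymphocytes and NK cells, B cells, plasma cells, monocytes, CD16 monocytes, plasmacytoid and conventional dendritic cells, immature granulocytes, mature neutrophils, platelets and megakaryocytes, erythroid cells and reticulocytes, and basophils and eosinophils. Of these lists, 8 shared 1 member each with another list and the others shared 0. Lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 28 lists of a comparison. Camera with an estimated correlation and fry were alternatives. A list value is the median log2 difference of its measured members.

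The alternatives fixed in advance were quantile normalization, no filter or a filter at the 60th percentile, the mean of all probe sets of a gene, an intensity trend with a robust prior, an unadjusted p under 0.01 with a change of at least 2-fold, fits over only the groups compared or over all 14 arrays, controls averaged over both sets, the mean of the 4 arrays of each donor, the replicate block, and leaving out each array or donor in turn. A further pair was chosen after seeing the data. In one, the set 2 arrays of the same control people replaced their set 1 arrays after quantile normalization over all 14 arrays. In the other, each array was centred on its median for the comparison of the controls.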

Results

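Gene expression was compared between post-partum donors and non-pregnant controls in peripheral blood mononuclear cells, the lymphocytes and monocytes isolated from blood. Set 1 held 2 controls and 2 post-partum donors, and each of these donors was sampled at 2, 4, 12 and 24 weeks after delivery. Set 2 held arrays of the same 2 control people and of 2 other post-partum donors at 2 weeks. The 14 arrays formed 7 groups of 2. Donors and controls are named by their replicate number in a set. The title of the series speaks of prolonged activation of an innate antiviral programme after childbirth. Across genes, the 2 control arrays of set 1 correlated with each other at 0.985 and those of set 2 at 0.989, whereas control arrays of different sets correlated at 0.956 to 0.959. Post-partum arrays of set 1 correlated with the set 2 controls at 0.962 to 0.975 and with their own controls at 0.955 to 0.974. Because the set 1 control arrays stood apart in this way, each count against them is given beside that against the same people's set 2 arrays. This alternative was chosen after seeing the data. It sets donors of set 1 against controls of set 2, so differences between the sets are confounded with the post-partum state. The control people alone differed between the sets in 2763 genes after quantile normalization. Calls kept, lost or reversed in this alternative therefore cannot separate the set from the post-partum state.

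At 2 weeks in set 1, markers of immature granulocytes and of erythroid cells were higher than in the controls, and markers of platelets were lower. Of 14 measured immature granulocyte markers, 13 were higher, with a median log2 difference of 1.81. The granulocyte progenitor gene MS4A3 was higher by 3.46 ± 0.66, the adhesion gene CEACAM1 by 2.12 ± 0.45 and LTF, which encodes the granule protein lactoferrin, by 3.64 ± 0.87 (n = 2 against 2 for this and all differences at a single time). All 11 erythroid markers were higher, with a median of 1.79, among them the haem synthesis gene ALAS2 (3.22 ± 0.77) and the globin genes HBD (3.51 ± 0.85) and HBB (2.78 ± 0.71). Of 19 platelet markers, 18 were lower, with a median of -0.74, and MYL9, a myosin light chain of platelets, fell by 1.39 ± 0.23 (adjusted p = 0.042). The camera test gave adjusted p = 9.63e-05 for immature granulocytes, 8.47e-06 for erythroid cells and 6.75e-07 for platelets. These became adjusted p = 0.832, 0.677 and 0.677 with an estimated correlation. Adjusted over all genes, 0 immature granulocyte and 0 erythroid markers and 1 platelet marker passed in limma. Adjusted over the list alone, 8, 8 and 6 passed. Against the set 2 arrays of the control people, the medians were 1.04, 1.48 and -0.79, with camera adjusted p = 0.000931, 0.000173 and 9.77e-07. The immature granulocyte median was 1.13 without the replicate 1 donor, and the erythroid median was 1.00 without the replicate 2 donor.

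Type I interferon-stimulated genes, which mediate antiviral defence, were higher at 2 weeks for 54 of 56 measured members, with a median of 0.79. TRIM5, a restriction factor of retroviruses, rose by 2.03 ± 0.27 (adjusted p = 0.0272) and RIGI, a sensor of viral RNA, by 1.81 ± 0.28 (adjusted p = 0.0402). In the set 2 arrays of the control people, TRIM5 was 2.00 and RIGI 0.81 higher than in their set 1 arrays. These values are relative to the median shift of all genes between the control arrays. SAMD9 (1.30 ± 0.24, adjusted p = 0.0518) and the death ligand gene TNFSF10 (3.09 ± 0.63, adjusted p = 0.0636) did not pass. Neither did OAS1 (2.58 ± 0.93), IFIT1 (2.56 ± 1.81), RSAD2 (1.80 ± 1.53), IFI44L (1.70 ± 1.92) and ISG15 (1.12 ± 0.98). In all, 2 members passed over all genes and 6 adjusted over the list alone, with camera adjusted p = 1.22e-06 and adjusted p = 0.832 with an estimated correlation. Against the set 2 arrays of the control people the median was 0.43 (camera adjusted p = 0.0956), and it was 0.46 without the replicate 1 donor. Interferon-gamma-induced genes had a median of 0.64 (camera adjusted p = 0.000648, adjusted p = 0.832 with an estimated correlation). The MHC class II regulator CIITA rose by 1.06 ± 0.17 and the guanylate-binding protein gene GBP4 by 1.65 ± 0.26, while GBP5 (a fold change of 2.64, adjusted p = 0.0687) did not pass. Without the replicate 1 donor the median of the interferon-gamma list was 0.25 (adjusted p = 0.121). B cell markers had a median of 0.78, with CD79B, a chain of the antigen receptor complex, up by 1.26 ± 0.17 and FCRL1 by 2.21 ± 0.33 (camera adjusted p = 2.16e-05, adjusted p = 0.677 with an estimated correlation). The B cell median was 0.09 against the set 2 arrays of the controls (camera adjusted p = 0.368).

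The largest rises past the threshold at 2 weeks were those of the fractalkine receptor gene CX3CR1 (3.29 ± 0.46, a fold change of 9.81), the cytokine signalling inhibitor SOCS2 (3.04 ± 0.43), ARFIP1 (2.60 ± 0.30), GAPT (2.60 ± 0.31), GIMAP4 (2.51 ± 0.26), SAC3D1 (2.41 ± 0.19), SLAMF6 (2.37 ± 0.41) and NHSL2 (2.30 ± 0.42). The largest falls were those of ASPH (-2.12 ± 0.38), the TGF-beta signalling inhibitor SMAD7 (-2.01 ± 0.33), IFITM10 (-1.93 ± 0.31), FAM20C (-1.87 ± 0.23), the neutrophil-attracting chemokine gene CXCL5 (-1.86 ± 0.31), MN1 (-1.76 ± 0.25), SH3BP4 (-1.74 ± 0.19) and SNX9 (-1.70 ± 0.14). Limma called 189 of 14015 genes, 151 higher and 38 lower. The count was 0 against the set 2 arrays of the controls and 0 without any 1 of the 4 arrays compared. Against those set 2 arrays the CX3CR1 difference was -0.16, SLAMF6 -0.24, NHSL2 -0.33, IFITM10 0.12 and SNX9 0.07. These are the ones that changed sign among the rises and falls named here, and the others did not where measured. MN1 and SH3BP4 were above the filter in only 2 of the 4 fits with 1 array left out.

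Further lists passed at 2 weeks in camera and failed with an estimated correlation, where adjusted p = 0.677 for basophils and eosinophils, 0.905 for inflammatory genes, 0.84 for glucocorticoid-responsive genes and 0.832 for the others. Mature neutrophil markers had a median of 1.30 (adjusted p = 0.00636), and the leukocyte protease gene MMP25 rose by 1.06 ± 0.17. Basophil and eosinophil markers had a median of 1.65 (adjusted p = 0.0138), with the mast cell protease gene CPA3 at 2.12 ± 0.50, IL5RA at 1.41 ± 0.28 and the granule protein gene PRG2 at -1.52 ± 0.25, past the threshold. Inflammatory cytokine and NF-kB target genes had a median of -0.72 (adjusted p = 0.0136) and cell cycle genes one of 0.38 (0.0136). The medians were 0.19 (0.0276) for MHC class I genes, -0.30 (0.0374) for plasmacytoid dendritic cell markers, 0.41 (0.0448) for interferon receptor and sensing genes and -0.37 (0.0448) for glucocorticoid-responsive genes. In the MHC class I list the immunoproteasome gene PSMB9 rose by 1.28 ± 0.22 and the peptide transporter gene TAP1 by 0.93 ± 0.16. Leaving out the replicate 1 donor ended the calls of mature neutrophils (0.85, adjusted p = 0.201), cell cycle (0.24), MHC class I (0.07) and interferon receptors (0.16). Without the replicate 2 donor, inflammatory genes (0.10), glucocorticoid-responsive genes (0.15) and plasmacytoid dendritic cells (-0.32) did not. Without control replicate 1, glucocorticoid-responsive genes (-0.35) did not pass. Without control replicate 2, cell cycle (0.32), glucocorticoid-responsive genes (-0.42), interferon receptors (0.41), MHC class I (0.18) and plasmacytoid dendritic cells (-0.13) did not. The inflammatory median turned to 0.69 with the set 2 arrays of the controls and did not pass (adjusted p = 0.118). Basophils and eosinophils (0.59), MHC class I (0.03), interferon receptors (0.11) and glucocorticoid-responsive genes (-0.25) did not pass there either.

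At 4 weeks in set 1, the median of the interferon-stimulated genes was 1.31 and that of the platelet markers -1.47. Of the 56 interferon-stimulated genes, 55 were higher. TNFSF10 rose by 3.37 ± 0.63 (adjusted p = 0.0474), a fold change of 10.3, TRIM5 by 2.30, RIGI by 2.22 and the interferon-induced genes SAMD9 and SP110 by 1.63 and 1.42. IFIT1 (3.41 ± 1.81), OAS1 (2.88 ± 0.93), RSAD2 (2.77 ± 1.53), IFI44L (2.61 ± 1.92) and ISG15 (1.89 ± 0.98) did not pass. Over all genes 5 members passed and 18 adjusted over the list alone (camera adjusted p = 2.25e-13, adjusted p = 0.705 with an estimated correlation). The median was 0.89 against the set 2 arrays of the controls (camera adjusted p = 4.24e-05). It was 0.41 without the replicate 1 donor and 2.26 without the replicate 2 donor. All 19 platelet markers were lower, and 9 passed over all genes and 14 adjusted over the list alone. Among the 9 were CAVIN2 (-2.09 ± 0.20), MYL9 (-2.21 ± 0.23), the matrix protein gene SPARC (-2.13 ± 0.22), the tubulin gene TUBB1 (-1.84 ± 0.25) and the chemokine gene PF4 (-1.94 ± 0.31). The platelet list passed (camera adjusted p = 5.97e-18, adjusted p = 0.383 with an estimated correlation). PPBP, which encodes a platelet chemokine precursor, stood at -1.64 ± 0.39 (adjusted p = 0.0861) and HBB at 1.44.

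B cell markers had a median of 1.10 at 4 weeks (camera adjusted p = 4.07e-06, adjusted p = 0.705 with an estimated correlation), with CD79B at 1.33 and FCRLA at 2.05 both past the threshold. With the set 2 arrays of the controls the median was 0.20 (camera adjusted p = 0.184), and without the replicate 2 donor it was 0.66. Interferon-gamma-induced genes had a median of 0.83 (camera adjusted p = 2.11e-05, adjusted p = 0.705 with an estimated correlation), with rises of CIITA (1.32), GBP4 (1.94), GBP5 (1.93) and APOL3 (0.83). Their median was 0.11 without the replicate 1 donor. The largest rises were those of CX3CR1 (3.37 ± 0.46), TNFSF10, GAPT (2.73), GIMAP4 (2.62), ARFIP1 (2.59), SOCS2 (2.49), TRIM69 (2.35 ± 0.28) and IGHD (2.33 ± 0.33), the heavy chain gene of immunoglobulin D. The largest falls were those of ASPH (-2.78 ± 0.38), ZNF697 (-2.22 ± 0.38), MYL9, CXCL5 (-2.13), SPARC, CAVIN2, MAP3K7CL (-2.00 ± 0.35) and PF4. Limma called 249 genes, 171 higher and 78 lower, against 22 (4 higher and 18 lower) with the set 2 arrays of the controls, of which 5 were shared. CX3CR1 stood at -0.07 there, and the other large rises and falls named did not change sign where measured. The count was 149 without the replicate 1 donor, 6 without the replicate 2 donor and 0 without either control.

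MHC class I genes (median 0.30, camera adjusted p = 0.00185), inflammatory genes (-0.68, 0.00971), plasmacytoid dendritic cell markers (-0.44, 0.0188), cell cycle genes (0.30, 0.0194), glucocorticoid-responsive genes (-0.51, 0.0194) and interferon receptor and sensing genes (0.45, 0.0326) also passed at 4 weeks. With an estimated correlation, adjusted p = 0.971 for inflammatory genes, 0.867 for glucocorticoid-responsive genes and 0.705 for the others. Cell cycle (0.11), interferon receptors (0.26) and MHC class I (0.15) lost their calls without the replicate 1 donor. Glucocorticoid-responsive genes (-0.06), inflammatory genes (0.07) and plasmacytoid dendritic cells (-0.37) lost theirs without the replicate 2 donor, and without control replicate 2 cell cycle (0.27), interferon receptors (0.41) and plasmacytoid dendritic cells (-0.29) did. The inflammatory median turned to 0.56 with the set 2 arrays of the controls (adjusted p = 0.253), and that of interferon receptors to -0.03. MHC class I (0.15) and glucocorticoid-responsive genes (-0.28) lost their calls there.

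At 12 weeks in set 1, platelet markers had a median of -1.23 and B cell markers a median of 1.20. MYL9 fell by 1.87, SPARC by 1.58, CAVIN2 by 1.39 and the neurogranin gene NRGN by 1.23. In all, 4 platelet markers passed over all genes and 13 adjusted over the list alone (camera adjusted p = 1.24e-13, adjusted p = 0.554 with an estimated correlation). FCRL1, a receptor-like gene of B cells, rose by 2.82 (a fold change of 7.08) and CD79B by 1.66. In all, 3 B cell markers passed over all genes and 11 adjusted over the list alone (camera adjusted p = 3.68e-09, adjusted p = 0.554 with an estimated correlation). With the set 2 arrays of the controls the medians were -1.22 for platelets (camera adjusted p = 2.35e-11) and 0.44 for B cells (0.00737). Interferon-stimulated genes had a median of 0.79 and 53 of 56 were higher, with TRIM5 up by 2.05, RIGI by 1.88 and SAMD9 by 1.47, while SP110 stood at 1.16. Of this list 3 members passed over all genes and 5 adjusted over the list alone (camera adjusted p = 6.71e-07, adjusted p = 0.883 with an estimated correlation). The median against the set 2 arrays of the controls was 0.43 (0.183), and it was 0.37 without the replicate 1 donor. IFIT1 (2.52), OAS1 (2.44), RSAD2 (2.18), IFI44L (2.05), ISG15 (1.21), HBB (2.30 ± 0.71) and PPBP (-1.16) did not pass.

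The other large rises at 12 weeks were those of CX3CR1 (3.38), SOCS2 (2.94), ARFIP1 (2.77), the immunoglobulin heavy chain genes IGHD (2.68) and IGHM (2.30 ± 0.34), GIMAP4 (2.51) and GAPT (2.42). The largest falls were those of CXCL5 (-2.18), IFITM10 (-1.95), MN1 (-1.93), MYL9, SNX9 (-1.80), FAM20C (-1.69), SCML1 (-1.63 ± 0.20) and VEPH1 (-1.63 ± 0.21). Limma called 109 genes, 86 higher and 23 lower. It called 0 against the set 2 arrays of the controls, where CX3CR1 stood at -0.07 and IFITM10 at 0.10, and 0 without any 1 of the 4 arrays compared. The other large rises and falls named at 12 weeks did not change sign against those set 2 arrays, where measured. MN1 and VEPH1 were above the filter in only 2 of the 4 fits with 1 array left out. Interferon-gamma-induced genes (0.42, camera adjusted p = 0.0113), inflammatory genes (-0.66, 0.0178), glucocorticoid-responsive genes (-0.48, 0.0286), regulatory T cell markers (0.32, 0.035) and plasmacytoid dendritic cell markers (-0.41, 0.0404) passed, each with adjusted p = 0.883 with an estimated correlation. In the regulatory T cell list, the transcription factor gene IKZF2 rose by 1.85 ± 0.28 and the interleukin-2 receptor gene IL2RA by 1.22 ± 0.19. Relative to the median shift, IKZF2 was 1.76 and IL2RA 0.70 higher in the set 2 than in the set 1 arrays of the control people. At 4 weeks, where the list was not called, the other measured members, FOXP3 (0.16), CTLA4 (-0.05), CCR4 (-0.33) and TNFRSF18 (0.00), did not pass. Their values at 12 weeks are not given here. The interferon-gamma median was 0.15 without the replicate 1 donor. Without the replicate 2 donor the medians were -0.27 for glucocorticoid-responsive genes, -0.08 for inflammatory genes, -0.38 for plasmacytoid dendritic cells and 0.24 for regulatory T cells. None of these passed. Regulatory T cells (0.26) also lost their call without control replicate 1 and plasmacytoid dendritic cells (-0.26) without control replicate 2. Against the control people's set 2 arrays, the inflammatory median turned to 0.63 (adjusted p = 0.194). Interferon-gamma-induced genes (0.31), glucocorticoid-responsive genes (-0.17), regulatory T cells (0.20) and plasmacytoid dendritic cells (-0.28) lost their calls there.

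At 24 weeks in set 1, the median of the interferon-stimulated genes was 0.63 and that of the platelet markers -1.43. TRIM5 rose by 2.01 and RIGI by 1.68, whereas SAMD9 (1.13), SP110 (1.08), OAS1 (2.27), IFIT1 (a fold change of 2.83), RSAD2 (1.10), IFI44L (1.04 ± 1.92) and ISG15 (0.90) did not pass. Of the interferon-stimulated genes 50 of 56 were higher, 2 passed over all genes and 4 adjusted over the list alone (camera adjusted p = 0.00173, adjusted p = 0.934 with an estimated correlation). The list median was 0.18 without the replicate 1 donor (adjusted p = 0.106) and 0.21 against the set 2 arrays of the controls (0.897). Among platelet markers, MYL9 fell by 2.08, CAVIN2 by 1.46 and the integrin gene ITGB3 by 2.17 ± 0.31. In all, 9 passed over all genes and 15 adjusted over the list alone (camera adjusted p = 4.17e-17, adjusted p = 0.421 with an estimated correlation). The platelet median was -1.33 against the set 2 arrays (5.82e-16). B cell markers had a median of 1.22 (camera adjusted p = 7.56e-07, adjusted p = 0.885 with an estimated correlation) and 0.33 against the set 2 arrays (0.154). Inflammatory genes (-0.69, camera adjusted p = 0.00211) and markers of cytotoxic lymphocytes and NK cells (0.59, 0.0191) had adjusted p = 0.934 with an estimated correlation. The perforin gene PRF1 stood at 1.18 ± 0.30 and the granzyme gene GZMA at a fold change of 2.64. The cytotoxic median was -0.12 without the replicate 1 donor and 0.28 without control replicate 1, and the inflammatory median was -0.35 without the replicate 2 donor, none past the threshold. Both lists changed sign with the set 2 arrays of the controls, to 0.62 (adjusted p = 0.54) for inflammatory genes and -0.35 (0.329) for cytotoxic cells.

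The largest rises at 24 weeks were those of CX3CR1 (2.87), ARFIP1 (2.65), GIMAP4 (2.34), IGHD (2.32), FCRL1 (2.29), SOCS2 (2.25), SMIM14 (2.22 ± 0.24) and ZNF585B (2.18 ± 0.26). The largest falls were those of ASPH (-2.71), ERMN (-2.30 ± 0.43), ITGB3, MYL9, IFITM10 (-2.06), ZNF697 (-1.94), LOC145474 (-1.87 ± 0.21) and SMAD7 (-1.86). PPBP (-1.60 ± 0.39, adjusted p = 0.0796) and HBB (0.75) did not pass. Limma called 284 genes, 218 higher and 66 lower, against 0 with the set 2 arrays of the controls and 0 without any 1 of the 4 arrays compared. With the set 2 arrays CX3CR1 stood at -0.58, IFITM10 at 0.02, SMIM14 at -0.10 and ZNF585B at -0.06. The other large rises and falls named at 24 weeks did not change sign there, where measured.

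Over the mean of the 4 times in set 1, platelet markers were lower and B cell markers and interferon-stimulated genes were higher. MYL9 fell by 1.89 ± 0.18, CAVIN2 by 1.47 ± 0.16, SPARC by 1.60 ± 0.18 and PPBP by 1.26 ± 0.31 (n = 8 arrays of 2 donors against 2 arrays). The counts of members given here take the 8 arrays as separate. With the mean of the 4 arrays of each donor, limma called 0 genes. Of the platelet markers, 13 of 19 passed over all genes and 16 adjusted over the list alone (median -1.20, camera adjusted p = 6.59e-14, adjusted p = 0.62 with an estimated correlation). CD79B rose by 1.43 ± 0.13, FCRL1 by 2.39 ± 0.26 and FCRLA by 1.89 ± 0.24. There, 7 of 14 B cell markers passed over all genes and 11 adjusted over the list alone (median 1.02, camera adjusted p = 6.99e-07, adjusted p = 0.858 with an estimated correlation). TRIM5 rose by 2.10 ± 0.21, RIGI by 1.90 ± 0.22, SAMD9 by 1.38 ± 0.19 and SP110 by 1.20 ± 0.20. In this list, 7 of 56 interferon-stimulated genes passed over all genes and 13 adjusted over the list alone (median 0.86, camera adjusted p = 7.94e-08, adjusted p = 0.858 with an estimated correlation). Compared with the set 2 arrays of the controls, the medians were -1.25 for platelets (camera adjusted p = 1.45e-12), 0.23 for B cells (0.0741) and 0.50 for interferon-stimulated genes (0.0663). The interferon median was 0.37 without the replicate 1 donor. OAS1 (2.54 ± 0.74), IFIT1 (2.50 ± 1.43), RSAD2 (1.96 ± 1.21), IFI44L (1.85 ± 1.52), CXCL10 (1.43 ± 0.90), ISG15 (1.28 ± 0.78), USP18 (0.99 ± 0.56), MX1 (0.83 ± 0.84), IFI27 (0.52 ± 0.53), IRF7 (0.42 ± 0.58), HBB (1.82 ± 0.56), CCR7 (-0.05 ± 0.40) and FKBP5 (-0.35 ± 0.19) did not pass.

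The interferon signal in set 1 was carried mainly by 1 donor in the values per array. In the replicate 1 donor the list median above the controls was 1.17, 2.26, 1.23 and 0.99 at 2, 4, 12 and 24 weeks, and 56, 56, 56 and 52 of the 56 genes exceeded both controls. In the replicate 2 donor it was 0.46, 0.41, 0.37 and 0.18, and 35, 34, 35 and 30 genes exceeded both controls. Monocyte markers were also higher in the replicate 1 donor than in the replicate 2 donor, by 0.84 as the mean of the 4 times, against 1.06 for the interferon list. Platelet markers were lower in both donors at each time, at -0.81, -1.38, -1.23 and -1.15 in replicate 1 and -0.61, -1.65, -1.21 and -1.62 in replicate 2. Inflammatory genes were near the controls in replicate 1 (0.10, 0.10, -0.08 and -0.35) and lower in replicate 2 (-1.35, -1.43, -1.25 and -0.96).

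**Figure D1:**
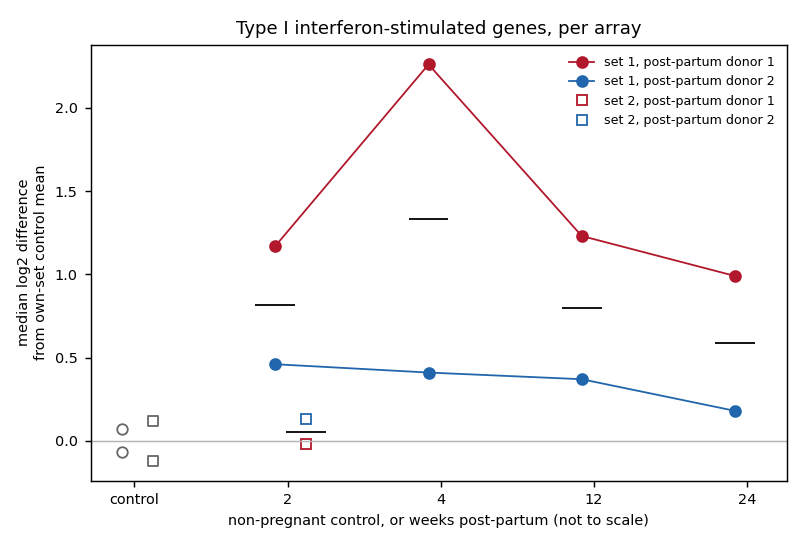
Median log2 difference of the type I interferon-stimulated genes from the controls of the same set (vertical axis) for each array, by control or weeks after delivery (horizontal axis, not to scale). Filled circles are the 2 donors of set 1 (red, replicate 1, highest at 2.26 at 4 weeks; blue, replicate 2, between 0.18 and 0.46), open squares are the donors of set 2 (-0.02 and 0.13), gray open markers are controls and black bars are the mean of 2 donors.

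The largest rises over the mean of the 4 times were those of CX3CR1 (3.23 ± 0.36), FCRL3 (2.93 ± 0.51), TNFSF10 (2.81 ± 0.50), SOCS2 (2.68 ± 0.34), ARFIP1 (2.65 ± 0.24), MS4A3 (2.62 ± 0.52), GIMAP4 (2.50 ± 0.20) and GAPT (2.47 ± 0.25). The largest falls were those of the scavenger receptor gene OLR1 (-2.77 ± 0.49), the platelet chemokine gene PF4V1 (-2.76 ± 0.62), NRIP3 (-2.69 ± 0.58), the cholesterol exporter gene ABCA1 (-2.50 ± 0.59), TNFRSF21 (-2.50 ± 0.55), ASPH (-2.46 ± 0.30), ERMN (-2.14 ± 0.34) and ZFYVE16 (-2.10 ± 0.41). Limma called 1098 genes, 765 higher and 333 lower, and 682 with the person as a replicate block. With the mean of the 4 arrays of each donor in place of 8 arrays the count was 0. With the set 2 arrays of the controls it was 702, 324 higher and 378 lower, with 101 genes shared. There CX3CR1 stood at -0.22, NRIP3 at 1.11 and IFI27 at -0.02. The other large rises and falls named for the mean did not change sign there, where measured. The count was 3040 without the replicate 1 donor, where the spread came from the control arrays alone. It was 0 without control replicate 1 and 10 without control replicate 2.

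Interferon-gamma-induced genes (0.55, camera adjusted p = 0.00226), inflammatory genes (-0.60, 0.00619), MHC class I genes (0.21, 0.0331) and glucocorticoid-responsive genes (-0.41, 0.0493) passed over the mean of the 4 times, each with adjusted p = 0.858 with an estimated correlation. CIITA rose by 1.23 ± 0.13, GBP4 by 1.60 ± 0.20, PSMB9 by 1.34 ± 0.18 and TAP1 by 0.94 ± 0.13, and the stress-inducible gene IER3 fell by 1.08 ± 0.23. In the set 2 minus the set 1 arrays of the control people, CIITA stood at 0.78, GBP4 at 0.98, TAP1 at 1.01 and IER3 at -1.44, relative to the median shift. The interferon-gamma median was 0.19 and the MHC class I median 0.15 without the replicate 1 donor. The inflammatory median was -0.07 and the glucocorticoid median -0.09 without the replicate 2 donor. Without control replicate 1 the glucocorticoid list (-0.41, adjusted p = 0.0722) did not pass. The inflammatory median turned to 0.58 against the set 2 arrays of the controls (adjusted p = 0.207), where MHC class I (0.08) and glucocorticoid-responsive genes (-0.18) did not pass.

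From 2 to 24 weeks in set 1, where the differences use no control array, erythroid, immature granulocyte and platelet markers went to lower values in the same 2 donors. All 11 erythroid markers were lower at 24 weeks, with a median of -1.84, and the largest differences by p were those of XK (-2.11 ± 0.35), TRIM58 (-1.84 ± 0.31) and ALAS2 (-2.59 ± 0.77). Of 14 immature granulocyte markers 13 were lower, with a median of -1.15, among them LTF (-3.23 ± 0.87), the iron-binding lipocalin gene LCN2 (-2.08 ± 0.55) and the antimicrobial peptide gene CAMP (-1.43 ± 0.40). Platelet markers had a median of -0.64, with ITGB3 at -1.33 ± 0.31, the von Willebrand factor receptor gene GP1BA at -0.83 ± 0.19 and PPBP at -0.95 ± 0.39. Basophil and eosinophil markers had a median of -1.16 and mature neutrophil markers one of -0.86, with 14 of 15 lower. The camera test gave adjusted p = 1.47e-21, 6.33e-13, 1.99e-19, 1.08e-07 and 2.31e-05 for these lists in this order. This became adjusted p = 0.113, 0.219, 0.113, 0.113 and 0.753 with an estimated correlation. The threshold adjusted over the list alone was passed by 8 erythroid, 3 immature granulocyte, 2 platelet and 2 basophil and eosinophil markers, against 0 over all genes. The size of the differences depended on the donor. Without the replicate 1 donor the medians were -2.79 for erythroid, -0.96 for platelet, -2.05 for basophil and eosinophil and -1.30 for mature neutrophil markers. Without the replicate 2 donor they were -0.70, -0.32, -0.51 and -0.57. Each time then had 1 array, so the spread came from the set 1 control arrays alone and no calls are given. The 24-week array of the replicate 2 donor stood apart in the difference between 5' and 3' probe sets. It was 0.145 for GAPDH, against 0.343 to 0.481 at that donor's other times, and -1.07 for ACTB, against -0.875 to -0.76.

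**Figure D2:**
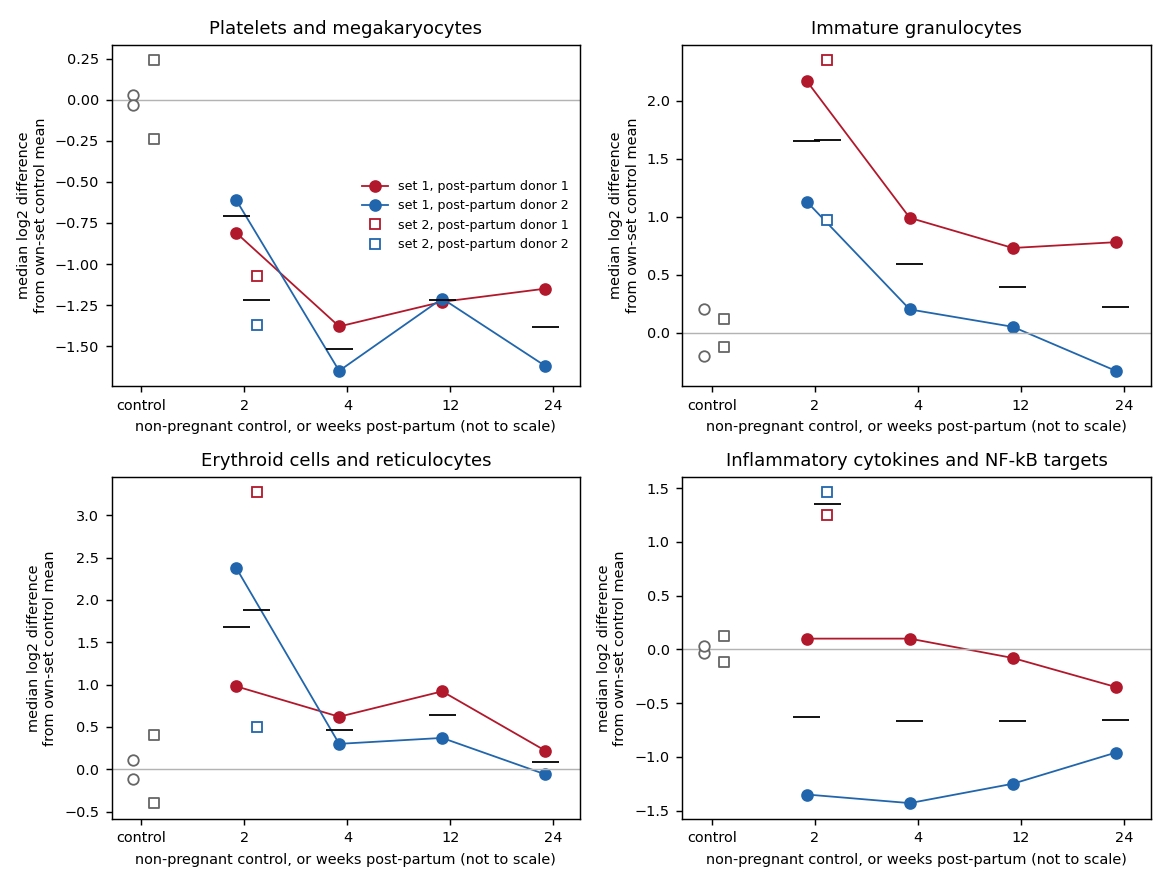
Median log2 difference of 4 gene lists from the controls of the same set (vertical axes) for each array, by control or weeks after delivery (horizontal axes, not to scale), with filled circles for the 2 donors of set 1, open squares for those of set 2, gray open markers for controls and black bars for the mean of 2 donors. Platelet values were below the controls in all post-partum arrays (-0.61 to -1.65), immature granulocyte values at 2 weeks were 2.17 and 1.13 in set 1 and 2.35 and 0.97 in set 2, erythroid values at 2 weeks were 0.98 and 2.38 in set 1 and 3.27 and 0.50 in set 2, and inflammatory values were 1.25 and 1.46 in set 2.

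Limma called 0 genes between 24 and 2 weeks, with 331 genes at an unadjusted p under 0.05. With the donor as a fixed block it called 1 gene, LTF (-3.23 ± 0.14, adjusted p = 0.00126). The largest positive differences, none of them called, were those of KIAA1671 (1.21 ± 0.29), MYOM2 (1.13 ± 0.33), PHEX (1.01 ± 0.19), the NK cell adhesion gene NCAM1 (0.84 ± 0.19), ABTB3 (0.82 ± 0.16), ERBB2 (0.81 ± 0.21), LINC01013 (0.81 ± 0.18) and AUTS2 (0.75 ± 0.20). The largest negative ones, likewise not called without the block, were those of LTF, XK, LCN2, TRIM58, CAMP, ITGB3, TMEM143 (-1.15 ± 0.32) and TTLL11 (-1.08 ± 0.29). HBB stood at -2.03 ± 0.71 and IFI44L at -0.66 ± 1.92. Interferon-stimulated genes had a median of -0.19, with 48 of 56 lower and TNFSF10 at -0.97 ± 0.63 (camera adjusted p = 0.00263, adjusted p = 0.918 with an estimated correlation). Cytotoxic lymphocyte and NK cell markers had a median of 0.49, with 18 of 18 higher (3.11e-05, adjusted p = 0.753 with an estimated correlation). Complement genes (-0.27, 0.00263), monocyte markers (-0.31, 0.00302), interferon-gamma-induced genes (-0.28, 0.00469), B cell markers (0.20, 0.0156) and interferon receptor genes (-0.12, 0.0236) also passed in camera. The first 3 had adjusted p = 0.806 and the last 2 adjusted p = 0.753 with an estimated correlation. The medians without the replicate 1 donor were -0.05 for interferon-stimulated, 0.08 for B cell, -0.22 for complement, -0.02 for cytotoxic and 0.01 for interferon-gamma-induced genes.

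At 2 weeks in set 2, platelet markers were lower and inflammatory, immediate early, immature granulocyte and erythroid genes were higher than in the controls. All 19 platelet markers were lower, with a median of -1.17, among them TUBB1 (-1.39 ± 0.16), NRGN (-1.39 ± 0.18) and CAVIN2 (-1.77 ± 0.23). Of 25 inflammatory genes 22 were higher, with a median of 1.41, among them the neutrophil-attracting chemokine genes CXCL2 (3.45 ± 0.16), CXCL1 (2.63 ± 0.14) and CXCL8 (2.30 ± 0.18). Of 24 immediate early and heat shock genes 22 were higher, with a median of 0.61, among them the transcription factor genes FOSB (1.54 ± 0.14), ATF3 (2.17 ± 0.20) and EGR3 (2.41 ± 0.37). All 16 immature granulocyte markers were higher, with a median of 1.63, among them the defensin gene DEFA4 (3.59 ± 0.46), the protease gene CTSG (1.62 ± 0.25) and CEACAM8 (3.47 ± 0.79). All 12 erythroid markers were higher, with a median of 1.73, among them HBD (3.34 ± 1.06), SLC4A1 (2.99 ± 1.28) and HBB (1.16 ± 0.54). The camera test gave adjusted p = 2.14e-17, 2.08e-17, 4.72e-15, 2.49e-12 and 0.000122 for these lists in this order. This became adjusted p = 0.634, 0.53, 0.339, 0.634 and 0.74 with an estimated correlation. Adjusted over the list alone, 14 platelet genes, 17 inflammatory genes (16 higher and 1 lower), 13 immediate early genes, 6 immature granulocyte markers and 0 erythroid markers passed, against 0 of each over all genes. The erythroid list did not pass without the replicate 1 donor (0.41, adjusted p = 0.338) or control replicate 2 (1.60, adjusted p = 0.111), and its median was 3.23 without the replicate 2 donor. The inflammatory median was 0.83 without the replicate 1 donor and 0.76 without the replicate 2 donor. The set 2 control arrays were themselves lower in these genes than the set 1 arrays of the same people. Relative to the median shift, the medians were -1.11 for inflammatory and -0.39 for immediate early and heat shock genes. The set 2 donors were not compared with the set 1 control arrays alone. The immature granulocyte median was 0.80 without the replicate 1 donor. CEACAM8 was above the filter in only 2 of the 4 fits with 1 array left out.

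Interferon-stimulated genes did not pass as a list in set 2, with a median of 0.02, 30 of 55 higher and 25 lower (camera adjusted p = 0.227, adjusted p = 0.887 with an estimated correlation). The members with the smallest p were the RNA sensor gene IFIH1 (-0.55 ± 0.14), PARP9 (0.42 ± 0.13), IFIT5 (-0.28) and SAMD9L (0.32), and none passed. IFIT1 (-0.05 ± 0.44), OAS1 (-0.18 ± 0.17), RSAD2 (0.38 ± 0.26), IFI44L (0.00 ± 0.36), ISG15 (0.10 ± 0.12), MX1 (0.04 ± 0.27), IFI27 (0.22), IRF7 (-0.19), CCR7 (0.31), FKBP5 (-0.49) and PPBP (-0.88 ± 0.15) did not pass either. With the controls averaged over both sets the list median was 0.29 (adjusted p = 2.83e-06). It passed in camera at 0.13 without the replicate 1 donor and at 0.16 without control replicate 2. Plasmacytoid dendritic cell markers were lower, with a median of -0.87 and 7 of 7 lower, led by the receptor gene LILRA4 (-1.45 ± 0.17), SERPINF1 (-1.54 ± 0.25) and PLD4 (-0.87). Over all genes 0 members passed and 4 adjusted over the list alone (camera adjusted p = 5.51e-06, adjusted p = 0.634 with an estimated correlation). Cell cycle genes (0.35, 2.95e-06), mature neutrophil markers (0.45, 0.000779), cytotoxic lymphocyte and NK cell markers (-0.57, 0.00119), interferon-gamma-induced genes (0.22, 0.0211) and conventional dendritic cell markers (-0.41, 0.0211) also passed in camera. In this order they had adjusted p = 0.634, 0.634, 0.742, 0.634 and 0.738 with an estimated correlation. In the cytotoxic list FGFBP2 stood at -1.54 ± 0.34 and the T cell coreceptor gene CD8B at 0.68 ± 0.11. The cell cycle median was 0.17 without the replicate 2 donor. Without the replicate 1 donor, conventional dendritic cells (-0.42), cytotoxic cells (-0.39) and neutrophils (0.32) lost their calls. Without control replicate 2, conventional dendritic (-0.23) and cytotoxic cells (-0.23) did. The interferon-gamma call ended without the replicate 2 donor (0.21) and without control replicate 1 (0.12).

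Limma called 1 of 13071 genes in set 2, APOBEC3B, a cytidine deaminase gene, which rose by 3.31 ± 0.11 (a fold change of 9.88, adjusted p = 0.0318). An unadjusted p under 0.05 was seen for 1019 genes. The count was 0 without any 1 of the 4 arrays. Other large differences that did not pass were those of DEFA4, CEACAM8, OLR1 (3.47 ± 0.35), CXCL2 (adjusted p = 0.0667), the prostaglandin synthase gene PTGS2 (3.12 ± 0.49), the cytokine gene IL1B (2.83 ± 0.34) and DOCK4 (2.69 ± 0.41) above the controls. Below the controls stood CXCL5 (-2.72 ± 0.22), MAP3K7CL (-2.08 ± 0.34), MFAP3L (-2.00 ± 0.12), RBPMS2 (-1.92), ELOVL7 (-1.89), CUTALP (-1.88), PTGDS (-1.81 ± 0.13) and PRKAR2B (-1.80 ± 0.17), which did not pass either. With 1 array left out, APOBEC3B, CEACAM8, OLR1, CXCL5, RBPMS2 and ELOVL7 were measured in only 2 of the 4 fits. In the others too few arrays were left above the filter, so APOBEC3B could not be called there.

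The test of the difference between the sets in the 2-week effect asked which genes responded differently in the donors of set 2 and of set 1. Effects at 2 weeks correlated between the sets at 0.07 across 14485 genes, which are not independent replicates. Inflammatory genes had a median difference of 1.76 (set 2 minus set 1) and immediate early genes one of 0.64. Interferon-stimulated genes had one of -0.77, with 54 of 56 lower in set 2, B cell markers one of -0.94 and basophil and eosinophil markers one of -1.78. In camera these lists had adjusted p = 1.2e-06, 0.00225, 9.83e-05, 0.00225 and 0.00797, and each had adjusted p = 0.898 with an estimated correlation. TRIM5 stood at -1.94 ± 0.36 and RIGI at -1.64 ± 0.34, and 2 interferon-stimulated genes passed adjusted over the list alone, against 0 over all genes. Without the replicate 1 donor of set 1 the interferon median was -0.31 (adjusted p = 0.0909), and without the replicate 2 donor of set 1 it was -1.28. The inflammatory median was 1.10 without the replicate 2 donor of set 1. Platelet markers (-0.46, 0.028), interferon receptors (-0.46, 0.028) and MHC class I genes (-0.26, 0.0337) also passed, with adjusted p = 0.898 with an estimated correlation. Each lost its call without at least 1 array, at -0.08 for platelets without control replicate 1 of set 2, -0.28 for interferon receptors and -0.13 for MHC class I without the replicate 1 donor of set 1. B cells (-0.32) lost theirs without control replicate 1 of set 2 and immediate early genes (0.27) without the replicate 2 donor of set 1.

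Limma called 10 genes for this difference, 4 higher and 6 lower, and 157 with the person as a replicate block. After quantile normalization it called 58, 14 higher and 44 lower. The positive differences were those of HTRA4 (2.69 ± 0.32), the apoptosis-associated translation inhibitor PDCD4 (2.04 ± 0.28), SNX9 (1.60 ± 0.19) and the apoptosis inhibitor BIRC2 (1.09 ± 0.15). The negative ones were those of the B cell and dendritic cell transcription factor BCL11A (-2.49 ± 0.24), SAC3D1 (-2.44 ± 0.34), SMIM14 (-2.30 ± 0.31), ZKSCAN3 (-2.29 ± 0.29), TMA16 (-2.00 ± 0.23) and the megakaryocyte transcription factor FLI1 (-1.81 ± 0.24). The count was 1 without either control array of set 2 and 0 without any other array of the 8 compared. Larger differences did not pass for OLR1 (5.85 ± 0.85, adjusted p = 0.05), COXFA4L3 (4.35 ± 1.27), DUSP4 (3.95 ± 1.07), RGS1 (3.90 ± 1.04), CLC (-4.37 ± 1.12) and TNFSF10 (-3.30 ± 0.84).

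The control arrays of set 2 were compared with those of set 1 to measure how far the sets differed in the same 2 people. The median shift was 0.638, and differences are given relative to it. CX3CR1 was 3.47 higher in the set 2 controls, CLC 2.95, FCRL3 2.79, BBS10 2.72, SLAMF6 2.66, NHSL2 2.64, ARFIP1 2.62 and MS4A3 2.62. OLR1 (-4.09), NRIP3 (-3.88), COXFA4L3 (-3.48), PHLDA1 (-3.43), CCL7 (-3.25), CTSL (-3.01), TREML3P (-2.72) and P2RY1 (-2.60) were lower. The difference between 5' and 3' probe sets of GAPDH was 0.145 to 0.516 on all set 1 arrays and -0.351 to -0.084 on all set 2 arrays. That of ACTB overlapped, at -1.07 to -0.724 and -0.788 to -0.542. In camera, 8 lists passed, each with adjusted p = 0.968 with an estimated correlation. Camera was run on the deposited scale, where the shift was not removed. It compares t statistics, so a list of genes with a wider spread can pass as lower. Its p-values therefore do not test the medians relative to the shift that are printed beside them. Relative to the shift, medians were lower in the set 2 controls for inflammatory genes (-1.11, adjusted p = 1.27e-17), immediate early and heat shock genes (-0.39, 9.71e-07), mature neutrophils (-0.22, 0.00257), monocytes (-0.17, 0.00431) and complement genes (-0.18, 0.00468), and higher for respiratory chain genes (0.25, 0.0016). Immature granulocytes (0.05, 0.0461) and erythroid cells (0.48, 0.0461) passed in the downward direction although their medians lay above the shift. Interferon-stimulated genes (0.50, 0.635), B cell markers (0.78, 0.678) and platelet markers (0.07, 0.752) did not pass. Among the interferon-stimulated genes called in set 1, TRIM5 stood at 2.00 and RIGI at 0.81 relative to the shift. Across genes, which are not independent replicates, the difference between the controls correlated with the change for the mean of the 4 times in set 1 at 0.72, with a covariance of 0.205. Simulated unchanged groups that shared the set 1 control arrays gave 0.63 and 0.052 over 20 draws, so part of the correlation comes from the shared arrays. On the deposited scale limma called 7884 of 14485 genes, 7790 higher and 94 lower. After quantile normalization it called 2763, 1348 higher and 1415 lower. With each array centred on its median, an alternative chosen after seeing the data, it called 3594, 1080 higher and 2514 lower.

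**Figure D3:**
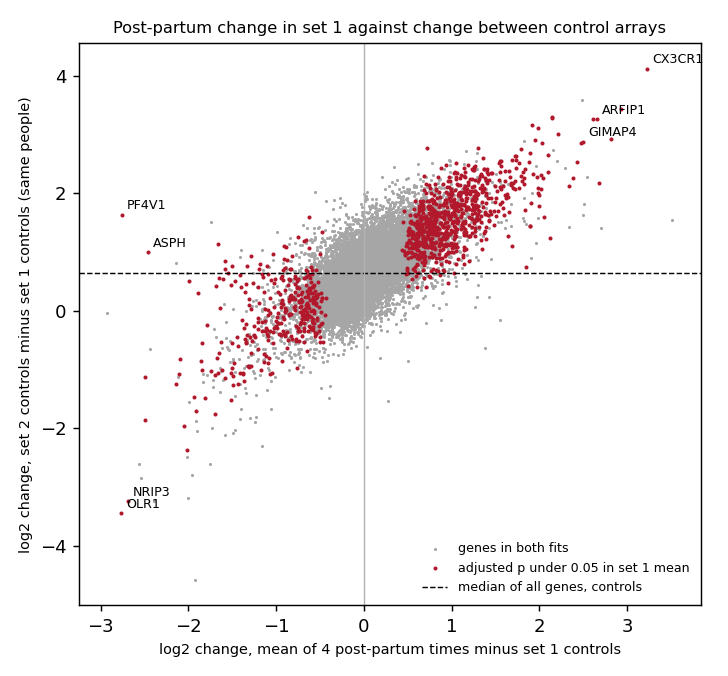
Log2 change of each of 13921 genes in set 1, as the mean of the 4 post-partum times minus controls (horizontal axis), against the log2 difference of the set 2 controls minus the set 1 controls of the same people (vertical axis). Red points are the 1097 genes past the threshold in set 1, gray points are the others and the dashed line is the median shift of 0.638.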

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

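All tests of explanations in this part were chosen after the results they bear on had been seen.

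The difference between the sets in the 2-week effect passed the threshold for 10 genes. The log2 effect in set 2 minus that in set 1 was 2.69 for HTRA4 (-1.52 in set 1 and 1.17 in set 2), 2.04 for PDCD4 (-0.99 and 1.05), 1.60 for SNX9 (-1.70 and -0.10) and 1.09 for BIRC2 (-0.36 and 0.73). It was -1.81 for FLI1 (1.51 and -0.30), -2.00 for TMA16 (2.08 and 0.08), -2.29 for ZKSCAN3 (2.22 and -0.08), -2.30 for SMIM14 (2.14 and -0.15), -2.44 for SAC3D1 (2.41 and -0.03) and -2.49 for BCL11A (1.72 and -0.77). The sets also differed in the median effect of 8 gene lists by camera, each with adjusted p = 0.898 with an estimated correlation. These medians were 1.76 for inflammatory cytokines and NF-kB targets, 0.64 for immediate early and heat shock genes, -0.26 for MHC class I antigen presentation, -0.46 for interferon receptors and nucleic acid sensing, -0.46 for platelets, -0.77 for type I interferon-stimulated genes, -0.94 for B cells and -1.78 for basophils and eosinophils. Each of these differences rests in part on the set 1 control arrays, and the sets also differed in the GAPDH difference between 5' and 3' probe sets (0.145 to 0.516 in set 1 and -0.351 to -0.084 in set 2), whereas that of ACTB overlapped (-1.07 to -0.724 and -0.788 to -0.542).

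The set 1 control arrays stood apart from the set 2 arrays of the same people. A deviation shared by the set 1 control arrays was tested by taking the donors minus 1 control person and the set 2 minus set 1 difference of the other control person, so that no array was used on both sides. The lower of the 2 correlations across genes was 0.55, consistent with such a shared deviation. Separate scaling of the sets that keeps the order of the genes as the whole cause was excluded, since the lower correlation was 0.55 after quantile normalization over all 14 arrays, against at most 0.01 in 20 simulated draws in which the controls of the sets differed by noise and an order-keeping rescaling alone. The post-partum state remains open for part of the genes. Of the 1098 genes called for the mean of the 4 times, 59.1% kept their direction against the set 2 controls. Their median difference there was 0.10 in place of 0.92. The same donor arrays entered both differences, which by itself favours the same direction, and the share expected from this was not estimated. The genes were chosen for their difference from the set 1 controls, which by itself lowers the median against any other control arrays. How much of the drop from 0.92 to 0.10 comes from this choice was not estimated either. The control deviation and the post-partum state cannot be told apart gene by gene because the series holds only 4 control arrays.

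The interferon-stimulated genes were highest in the replicate 1 donor of set 1, with a peak at 4 weeks. A higher share of monocytes at 4 weeks was excluded as the whole cause of the peak, since the interferon list rose above that donor's other times by 1.13, against 0.22 for the monocyte markers and a range of 0.24 over the other times. As the whole cause of the rise above the controls at 4 weeks, any order-keeping scaling by the authors was excluded. The 56 members rose there by a median of 31.2 percentile ranks over the control mean, against 4 between the control arrays. The SE of the mean rise was 3.2 over the members, which are genes of 1 array and not independent replicates. Ranks were not compared with that donor's other times or with the other donor. The difference between the donors and their monocyte shares cannot be told apart, because the interferon difference (1.06) exceeded the monocyte marker difference (0.84) by 0.22 only (SE 0.13 over 4 times of the same donors). A biological difference between the donors, such as an infection or an inherited trait, was not tested.

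Immature granulocyte markers were higher at 2 weeks in both sets. Carry-over of mature neutrophils cannot be told apart in either set. The mature neutrophil median was at most 0.35 of the immature granulocyte median in set 2. In set 1 this ratio reached 0.83 in the replicate 1 donor. A ratio of log2 medians depends on the baseline signal of each list, and mature neutrophil markers also passed in camera in set 2. In set 1 the part of the control arrays cannot be told apart either: against the set 2 arrays of the control people the median was 1.04 (camera adjusted p = 0.000931, adjusted p = 0.818 with an estimated correlation), but it fell to 0.49 for the lowest pair of 1 donor and 1 control array. Release of immature granulocytes after delivery may account for the pattern and stays a hypothesis, because blood cell counts were not available.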

How the results depend on the processing

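The set 2 control arrays in place of the set 1 control arrays, and the centring of each array on its median, were chosen after seeing the data. Over all alternatives, 53 of 123 counts stayed within 1.5 times their value. Of the list results 842 of 1122 and of the gene results 1898 of 2488 kept their direction and their side of the threshold. Another 261 and 527 kept only their direction, 3 and 29 newly passed and 16 and 34 changed sign. Quantile normalization and the intensity trend with a robust prior changed no list call in any comparison. The number of arrays limits all results: at 2-fold, 27.8% of simulated genes were recovered at 2 weeks in set 1, in draws with independent arrays. Where an array left a group with 1 array, it was assumed to vary like the other groups. The filter was applied again to the arrays left, so the measured members of a list could change. Where a donor was left out of the mean or of 24 against 2 weeks, the spread came from the set 1 control arrays alone. No paired analysis was possible in set 2, because each person had 1 array in that fit. Except where fewer arrays or another threshold or filter was the change, the cause was not tested.

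With the set 2 control arrays, the counts were 0 at 2 weeks, 22 at 4 weeks, 0 at 12 weeks, 0 at 24 weeks and 702 for the mean of the 4 times. All donors then came from set 1 and all controls from set 2, so set and post-partum state were confounded. The interferon-stimulated medians that lost their calls were 0.43 at 2 weeks, 0.43 at 12 weeks, 0.21 at 24 weeks and 0.50 for the mean. The inflammatory median changed sign, to 0.69, 0.56, 0.63, 0.62 and 0.58 in the order 2, 4, 12, 24 weeks and mean, as did interferon receptors at 4 weeks (-0.03) and cytotoxic lymphocytes at 24 weeks (-0.35). CX3CR1 changed sign to -0.16, -0.07, -0.07, -0.58 and -0.22 in the same order. At 2 weeks SLAMF6 changed sign to -0.24, NHSL2 to -0.33, IFITM10 to 0.12 and SNX9 to 0.07, and at 12 weeks IFITM10 did to 0.10. At 24 weeks SMIM14 changed sign to -0.10, ZNF585B to -0.06, IFITM10 to 0.02 and HBB to -0.28, and for the mean NRIP3 did to 1.11 and IFI27 to -0.02. The cause was not tested for single genes. With controls averaged over both sets after quantile normalization, the count at 2 weeks in set 1 was 0 and the inflammatory median there was 0.05. In set 2 the interferon-stimulated median was 0.29 and passed, and IFIT1 (0.50), MX1 (-0.02) and OAS1 (0.60) changed sign.

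An unadjusted p under 0.01 with a 2-fold change gave 446, 478, 414, 508 and 541 genes at 2, 4, 12 and 24 weeks and for the mean, 11 for 24 against 2 weeks, 122 in set 2, 437 for the difference between sets and 3461 for the controls. A fit over only the groups compared gave 2, 0 and 243 genes at 2, 4 and 12 weeks. A fit over all 14 arrays gave 673, 671, 561, 888 and 1850 at 2, 4, 12 and 24 weeks and for the mean, and 3 in set 2. The person as a block gave 682 for the mean, 1 for 24 against 2 weeks and 157 for the difference between sets, and the mean of each donor's arrays gave 0. The block changed no list call and moved no other count by more than 1.5 times. In set 2, quantile normalization gave 2, no filter 0, the 60th percentile filter 6 and the trend with a robust prior 2. IFI44L stayed at 0.00 after quantile normalization, with a change of sign below the rounding only. The difference between sets had 58 genes after quantile normalization, 5 with no filter, 26 with the 60th percentile filter, 3 with the mean of all probe sets and 6 with the trend and robust prior. The controls differed by 2763 genes after quantile normalization and 3594 after centring.

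With an estimated correlation or with fry, no interferon-stimulated call was kept, for medians of 0.79, 1.31, 0.79, 0.63 and 0.86 at 2, 4, 12 and 24 weeks and for the mean, -0.19 for 24 against 2 weeks and -0.77 between sets. The adjusted p ranged from 0.705 to 0.934 with an estimated correlation and from 0.334 to 0.973 with fry.

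Leaving out 1 array or donor at a time gave counts of 0 to 0 at 2, 12 and 24 weeks, 0 to 149 at 4 weeks, 0 to 3040 for the mean, 0 to 0 in set 2 and 0 to 1 between sets. The interferon-stimulated median ranged from 0.18 to 0.99 at 24 weeks, -0.36 to -0.05 for 24 against 2 weeks, -0.04 to 0.16 in set 2 and -1.28 to -0.31 between sets. Other lists that changed sign were glucocorticoid-responsive genes at 2 weeks (-0.82 to 0.15), inflammatory genes at 2 weeks (-1.35 to 0.10) and 4 weeks (-1.43 to 0.07), cytotoxic lymphocytes at 24 weeks (-0.12 to 1.34) and for 24 against 2 weeks (-0.02 to 1.03), and interferon-gamma-induced genes for the latter (-0.51 to 0.01). Genes that changed sign were HBB (-0.06 to 1.56) and IFI44L (-0.40 to 2.48) at 24 weeks, CCR7 (-0.47 to 0.36), IFI27 (-0.01 to 1.04), IRF7 (-0.19 to 1.03) and MX1 (-0.13 to 1.79) for the mean, and TTLL11 (-1.48 to 0.02) for 24 against 2 weeks. In set 2 they were IFIT1 (-0.63 to 0.53), IFI44L (-0.47 to 0.47), MX1 (-0.32 to 0.40) and OAS1 (-0.39 to 0.02).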

Other observations

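The comparisons with the set 2 arrays of the control people in this part were chosen after the results had been seen.

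Lists not described so far passed in no comparison of single times with the controls. For the mean of the 4 times, T cell markers had a median of 0.60 (camera adjusted p = 0.0546), with the CD3 chain gene CD3G up by 0.99 ± 0.24, naive T cell markers 0.56 (0.229), T cell inhibitory receptors 0.39 (0.231), CD16 monocyte markers 0.25 (0.513), plasma cell markers 0.14 (0.78), MHC class II genes 0.03 (0.887), ribosomal protein genes 0.02 (0.887) and respiratory chain genes 0.00 (0.676). Among members that passed, the B cell coactivator gene POU2AF1 rose by 1.54 ± 0.27 and the myeloid nuclear gene MNDA by 1.73 ± 0.35. Relative to the median shift, POU2AF1 was 1.58, MNDA 1.43 and CD3G 0.97 higher in the set 2 than in the set 1 arrays of the control people. In set 2 the medians were 0.07 for T cells (0.0831), 0.27 for naive T cells (0.0522), -0.30 for inhibitory receptors (0.187), -0.26 for CD16 monocytes (0.508), 0.22 for plasma cells (0.171), -0.06 for MHC class II (0.924), -0.02 for ribosomal proteins (0.924) and -0.12 for the respiratory chain (0.175).

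Of the lists called against the set 1 controls, 7 of 14 at 2 weeks, 5 of 10 at 4 weeks, 2 of 8 at 12 weeks, 1 of 5 at 24 weeks and 2 of 7 for the mean of the 4 times were also called against the set 2 arrays of the same people. Platelet markers were called at each of these, although set and post-partum state were confounded against the set 2 arrays. With an estimated correlation no list was called against the set 1 controls, and the platelet list had adjusted p = 0.677, 0.383, 0.554, 0.421 and 0.62 in the same order.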
